A study of Homo sapiens with 18 samples.

How the data were processed

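The series holds 18 samples of HEK293T, an established human embryonic kidney cell line, and 12 of them were used here. RNA-seq was made from 3 libraries of parental cells and 3 libraries of cells with a CRISPR-Cas9 knockout of UBR7 (UBR7KO). ATAC-seq, which reads chromatin open to a transposase, was made from 2 libraries of each. ChIP-seq was made for GFP in 1 library of cells whose own UBR7 gene carries a GFP tag, with 1 input library. The 6 CUT&RUN samples for H3K4me3 were not analysed here. The labels place 2 of the UBR7KO RNA libraries in line KO1 (KO1-1 and KO1-2) and 1 in line KO2 (KO2-1). The descriptions carry date codes that pair parental 1 with KO1-1 and parental 2 with KO1-2. Parental 3 and KO2-1 carry no date and were taken as an undated pair. The code of KO2-1 also stands in the descriptions of both UBR7KO ATAC libraries, so the use of line KO2 for ATAC was inferred and is not stated. Whether the replicates are separate cultures is not stated, and they may be technical.

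Per the labels' protocols, RNA was isolated with a column kit and libraries were made with the TruSeq LS protocol. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.1, edgeR, Bowtie, Bowtie2 2.3.1, MACS2, Trim Galore, Trimmomatic 0.36, Picard, SAMtools 1.3.1, bedtools and deepTools, and the builds hg19 and hg38, without a role for each. The coordinates in the deposited files run past the ends of some GRCh38 chromosomes, so positions are given in GRCh37-type coordinates counted from 1. The deposited RNA table holds CPM per library for 14177 genes, that is reads of a gene scaled by the authors to a fixed library total and by nothing else. Every value was a whole multiple of 1 step per library within a tolerance of 1e-06, so whole reads and library totals were recovered from the spacing of the values. The authors' log2 fold changes and mean log2 CPM stand in the same table, from an edgeR likelihood ratio test per the file headers. Its p-value and adjusted p columns were also written by the authors, and their design and adjustment are not stated. The deposited ATAC peak lists give the −log10 q of each broad peak, called by the authors in each library alone. The fold enrichment and −log10 p-value columns of the deposited ATAC lists hold numbers beyond any real range and were not used. The score of each region in the 2 replicate-intersected ATAC sets is the sum of the scores of the peaks the authors merged. The score in the deposited GFP-UBR7 peak list has no stated scale, so it was used only to rank peaks. The file of gene starts holds the authors' 4 cluster labels and no signal, so the planned summary of an ATAC value per gene region was not made.

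Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Because the table holds CPM and not counts, the rule fixed before the data were examined chose limma with an intensity trend and robust empirical Bayes on log2(CPM + 1), for the 13697 genes above 1 CPM in at least 3 libraries. Calls used a Benjamini-Hochberg adjusted p under 0.05. The groups were also compared with the date pair as a block and in the 2 dated pairs alone. Levels are means with their SD over the 3 libraries of a group. UBR7 was also compared by an exact two-sided permutation test. The named genes were to be UBR7, the 10 largest rises and 10 largest falls among called genes with mean log2 CPM of at least 1 and groups that do not overlap, up to 3 called members of each list or else its most expressed member, and CDH4, NASP, ASF1A, ASF1B, CHAF1A and HIRA. For ChIP they were the 5 peaks with the highest score and any peak in UBR7. Since no gene was called over all 6 libraries, the largest changes with the block and in the dated pairs were named after their values were seen.

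The 31 gene lists fixed before the data were examined were replication-dependent histones, replacement histone variants, histone chaperones and assembly factors, UBR box proteins, H3K4 methyltransferases and demethylases, H3K9 methylation and heterochromatin, Polycomb complexes, DNA replication, mitosis, p53 targets, interferon-stimulated genes, the integrated stress response, the unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, Wnt targets, cadherins and epithelial-mesenchymal genes, extracellular matrix, protocadherin clusters, HOX genes, the KRAB-type zinc finger family (taken as ZNF symbols), cancer-testis antigens, imprinted genes, neuronal and neuroendocrine genes, ribosomal proteins, mitochondrially encoded genes, and markers of fibroblasts, of keratinocytes or cervical epithelium, of blood and of a mouse or fly spike-in. Lists with at least 5 tested members were compared with the other genes by limma camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes.

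ATAC peaks were compared by number, covered length and overlap of at least 1 bp, beside 1000 circular shifts of each list within chromosomes. A gene start counted as open where a peak lay within 1 kb of it. The change in open starts was scored per gene as the number of UBR7KO libraries minus the number of parental libraries with a peak there, an added measure in place of the missing region value. GFP-UBR7 peaks were compared with ATAC peaks and gene starts in the same way, and with fixed lists by Fisher's exact test and by 10000 random lists matched in expression. Shares of peaks carry Wilson 95% confidence intervals, which cover counting error only. Library totals ran from 22153291 to 29811908 reads, and 3 reads amount to 0.101 to 0.135 CPM. The read depth behind the ATAC and GFP-UBR7 peak lists is unknown.

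The fits were tested on simulated data of the same size, with 50 genes changed at each of 4 sizes among 13674. Limma without the block recovered 0% of the genes changed by 1 on the log2 scale, 60% at 2, 100% at 3 and 96% at 4, with 0 false calls. With the block it recovered 98% at 1 and 100% at each larger size, with 5 false calls. The simulated changes were alike in every pair and in both lines, with a scatter common to all genes. These shares thus do not give the power in the real data, where changes differed between the pairs. Alternatives covered size factors, DESeq2, edgeR's exact test, limma-voom, the filter, a pseudocount of 0.1, thresholds, the block, and each library left out in turn. After the data were seen, edgeR likelihood ratio and quasi-likelihood tests, DESeq2 with the block, TMM-scaled values, CPM without the 4 most abundant RNAs, and the difference between lines KO1 and KO2 were added. Bins of 10 Mb with at least 20 tested genes were used to describe RNA level along chromosomes, a measure also added after the data were seen.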

Results

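RNA, open chromatin and the chromosomal sites of UBR7, a UBR box protein named in the series title as a chaperone of histone H3, were profiled in HEK293T cells. The 6 RNA-seq libraries held 27418953, 22153291 and 29141652 reads for parental 1, 2 and 3, and 26395544, 25487348 and 29811908 reads for KO1-1, KO1-2 and KO2-1. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 took between 15.8% (KO1-1) and 26.3% (KO2-1) of the reads. The transcript CTD-2328D6.1 took 6.13%, 5.47% and 0.0237% of reads in parental 1, 2 and 3, and 5.77%, 2.35% and 0.0136% in KO1-1, KO1-2 and KO2-1, so the undated pair stood apart from the dated pairs in both groups. Deviations of each UBR7KO library from its group mean followed those of the parental library of its own pair. The correlations across genes were 0.758 and 0.736 for the dated pairs and 0.633 for the undated pair, against −0.443 to −0.251 for other pairings. Each group was centred on its own mean, which ties these values together. The value of the undated pair thus largely follows from the others and is no separate support for that pairing. A chi-square of read counts over genes, which uses no group mean, was 35.4 and 45.4 per degree of freedom within the dated pairs. It was 33.7 between parental 3 and KO2-1, and 138.8 to 327.4 for every other 2 libraries, also those of 1 group. The undated libraries thus resembled each other as the dated partners did, which does not show that they were prepared together. Line contrasts, likelihood ratio and quasi-likelihood fits, TMM-scaled values, DESeq2 with the block, the score of open gene starts and the gene list test of GFP-UBR7 peaks were chosen after the data were seen.

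The targeted gene was read first, to see whether the knockout lines differ from parental cells in its RNA. UBR7 (ENSG00000012963, chromosome 14, 93673401 to 93695561) stood at 55.0, 62.2 and 62.2 CPM in the parental libraries, a mean of 59.8 ± 4.16 (SD, n = 3). It stood at 27.0 and 26.3 CPM in the KO1 libraries, 0.446 of the parental mean. In the library labelled KO2 it stood at 64.5 CPM, 1.08 of the parental mean. Within the 2 dated pairs UBR7 fell by 1.10 on the log2 scale (SE 0.13, limma adjusted p = 1.56e-05). Over all 6 libraries the log2 change was −0.72 (SE 0.33, limma adjusted p = 1), and with the date pair as a block the adjusted p was 0.814. The exact two-sided permutation test of the 6 values gave p = 0.4, where the smallest p that 3 against 3 libraries can give is 0.1. The change in the KO2 pair exceeded that in the KO1 pairs by 1.16 (log2, SE 0.22, limma adjusted p = 0.00176). That p rests on 1 KO2 library and 1 residual degree of freedom, and cannot part the line from the preparation of the undated pair.

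The comparison of UBR7KO with parental cells asked which transcripts depend on UBR7. SFRP1, a secreted antagonist of Wnt signalling (ENSG00000104332, chromosome 8), averaged 0.132 ± 0.0812 CPM in UBR7KO and 2.47 ± 0.316 CPM in parental cells (SD, n = 3 each). BMP2, a bone morphogenetic protein ligand (ENSG00000125845, chromosome 20), averaged 0.793 ± 0.462 against 5.03 ± 2.12 CPM, and SNX19, a sorting nexin (ENSG00000120451, chromosome 11), 0.806 ± 0.305 against 4.40 ± 1.91 CPM. BEX1 averaged 1.75 ± 0.360 against 13.4 ± 11.3 CPM, and ZNF883 0.373 ± 0.124 against 2.63 ± 0.790 CPM. UNCX, a homeobox transcription factor (ENSG00000164853, chromosome 7), averaged 16.6 ± 5.83 CPM in UBR7KO and 5.32 ± 2.86 CPM in parental cells. These 6 genes, singled out after their values were seen, were the ones that changed at least 2-fold the same way in all 3 date pairs on the log2(CPM + 1) scale. Turning the sign of 1 pair in turn left 0, 0 and 10 such genes. The SFRP1 level in KO1-2, 0.039 CPM, lay under the 0.118 CPM that 3 reads give, so its fold change depends on the pseudocount. The pseudocount of 1 also shrinks other changes from low levels, and with 0.1 in its place the log2 change went from −1.38 to −2.52 for ZNF883, from −1.73 to −2.56 for BMP2 and from −1.54 to −2.29 (−2.285) for SNX19.

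In the authors' deposited table, SFRP1, SNX19, BMP2, BEX1, ZNF462 and ZNF883 were the 6 genes lower at an adjusted p under 0.05, and 0 were higher. Their log2 changes in the authors' deposited table ran from −4.17 (SFRP1) to −2.45 (SNX19), with adjusted p from 1.34e-05 to 0.00622, and all 6 were also under 0.01. In the authors' deposited table UBR7 had a log2 change of −0.59 with an adjusted p of 1. Limma on the 13697 tested genes called 0 higher and 0 lower, with 23 higher and 47 lower at an unadjusted p under 0.05. DESeq2 called 1 gene higher (UNCX, adjusted p = 0.0472) and 6 lower, edgeR's exact test and likelihood ratio test each called 0 and 6, and edgeR quasi-likelihood and limma-voom called 0. The 6 genes of the authors' deposited table were all called by the likelihood ratio test here. Log2 changes across genes in the authors' deposited table and in the limma fit had a Spearman correlation of 0.970. With the date pair as a block, limma called 0 in each direction, with 473 higher and 282 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.0584 (BMP2). That excess of higher genes depends on scaling, since limma on TMM-scaled values gave 409 higher and 370 lower with the block and quasi-likelihood 411 and 370. On the same block, the likelihood ratio test called 19 higher and 40 lower, DESeq2 12 and 26, limma on TMM-scaled values 1 and 3, and quasi-likelihood 0. The UBR7KO and parental libraries did not overlap for 171 genes higher and 169 lower, 2.48% of tested genes. The 10% by chance holds for exchangeable libraries alone, and date pairs that move together make such separation rarer, so it is no benchmark here. BEX1 and ZNF462 in parental 3 stood at 26.5 and 29.9 CPM, far above the 6.82 to 9.07 CPM of the other parental libraries.

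**Figure D1:**
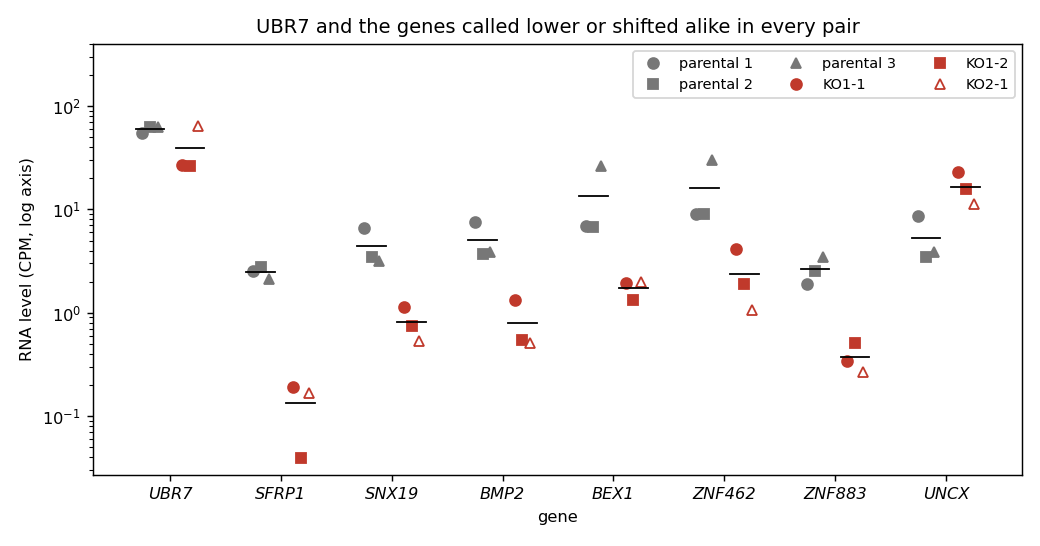
RNA level in CPM on a log axis of UBR7, the 6 genes called lower in the authors' deposited table and UNCX, with 1 point per library and a bar at the mean of each group of 3. UBR7 in the library labelled KO2 (64.5 CPM) sits with the parental libraries, while the other 7 genes sit apart in all 3 UBR7KO libraries.

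Within the 2 dated pairs, where KO1 was compared with parental cells of the same date, 305 genes rose and 186 fell (limma). APC2, a homologue of the tumour suppressor APC, rose by 2.57 (log2, SE 0.17, adjusted p = 5.17e-09), SYTL5 by 2.09 (SE 0.16, adjusted p = 2.35e-08) and COL6A3, a chain of collagen VI, by 1.77 (SE 0.21, adjusted p = 1.35e-05). UNCX, MXRA8, MLLT11, TMCO3, the collagen receptor DDR2, the intermediate filament gene NES and MID1 were the other 7 of the 10 largest rises, by 1.62, 1.54, 1.43, 1.36, 1.28, 1.19 and 1.17. CTSZ, a lysosomal cathepsin, fell by 3.11 (SE 0.22, adjusted p = 1.57e-08), MARVELD2, a protein of tricellular junctions, by 2.87 (SE 0.20, adjusted p = 9.64e-09), and the receptor phosphatase PTPRM changed by −2.62 (SE 0.21, adjusted p = 3.28e-08). ACSS3, RP11-453F18__B.1, MGST1, CPPED1, the epithelial splicing regulator ESRP2, ARHGAP20 and BMP2 were the other 7 of the 10 largest falls, from −2.56 to −1.73. Of the rises, MLLT11, DDR2 and NES lie on chromosome 1, which holds a stretch higher in KO1 by a median of 0.26, less than these rises. These genes were chosen after their values were seen. The pseudocount of 1 shrinks falls to low levels, as for CTSZ, at 0.152 and 0.235 CPM in KO1 against 6.53 and 13.1 CPM in the parental partners.

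The library labelled KO2 did not share most of these changes. MID1 stood at 336 and 320 CPM in the KO1 libraries against 147 and 143 in their parental partners, and at 21.0 CPM in KO2 against 93.9 in parental 3. MARVELD2 stood at 0.909 and 0.471 CPM in KO1 against 12.4 and 10.2, and at 24.2 in KO2 against 7.34. Of the 491 genes called in the dated pairs, 193 (39.3%) changed in the same direction in the undated pair. Of the 305 rises 36.7% were higher there, against 47.2% of all tested genes, and of the 186 falls 43.6% (43.55) were lower, against 52.8%. By at least 2-fold, 23 of them changed in the same direction there and 38 in the opposite one. Changes across genes correlated between the KO1 pairs (Spearman 0.348) and not with the KO2 pair (−0.0895 and −0.122), where genes are not independent replicates. In a test of the KO2 pair against the KO1 pairs with the date pair as a block (limma, 1 residual degree of freedom), 234 genes had a higher change in the KO2 pair and 455 a lower one, 212 of the 491 among them. edgeR quasi-likelihood called 238 rises and 244 falls in the dated pairs. These p-values measure the spread between libraries of 1 line, which may be technical replicates. A chi-square of read counts over genes was 143.9 per degree of freedom between KO1-1 and KO1-2 and 138.8 between parental 1 and 2. Counting error alone would give about 1, so these values argue against repeat sequencing of 1 library. Separate libraries of 1 culture remain possible. KO2 has 1 library, in the undated pair alone, so line and preparation cannot be parted, and the genes named here were picked for large KO1 changes.

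Gene lists asked whether pathways moved together. Genes of cholesterol synthesis were higher in UBR7KO for 22 of 23 tested members, with a median log2 change of 0.37 and medians of 0.46, 0.26 and 0.43 (0.425) in the pairs of KO1-1, KO1-2 and KO2-1. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, averaged 222 ± 35.1 CPM in UBR7KO and 134 ± 72.8 in parental cells. The isomerase IDI1 averaged 118 ± 13.6 against 73.6 ± 16.7 CPM, and farnesyl diphosphate synthase FDPS 139 ± 8.12 against 95.4 ± 11.3 CPM. INSIG1 lies in a bin of chromosome 7 (150 to 160 Mb) higher by a median of 0.386 in the KO2 pair. INSIG1 itself changed by 1.14, 0.27 and 1.12 in the pairs of KO1-1, KO1-2 and KO2-1. IDI1 lies on chromosome 10, where every bin lay above 0 in the KO1 pairs. The list was not tested with such shifts taken out. SC5D was the member with a negative change, −0.24. The list was called higher by camera (adjusted p = 4.56e-17), with an adjusted p = 0.0849 with an estimated correlation and a fry adjusted p of 0.721. With each library left out in turn its adjusted p ran from 4.62e-20 to 0.00273. Over all 6 libraries 0 members passed over all genes and 0 adjusted over the list alone. With the block 12 were higher adjusted over the list alone, and in the dated pairs 5 passed over all genes and 13 rose and 1 fell adjusted over the list alone.

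The p53 target list was called lower (adjusted p = 0.00149), with 19 of 24 members lower and a median of −0.18, and its adjusted p = 0.857 with an estimated correlation. Its pair medians were −0.40 and −0.10 (−0.0991) in KO1 and 0.15 in KO2. AEN averaged 55.3 ± 19.1 CPM in UBR7KO and 75.7 ± 29.7 in parental cells, and CCNG1, the most expressed member, 373 ± 40.7 against 384 ± 104. Without parental 1 the adjusted p of the p53 list was 0.627. The unfolded protein response list was called higher (adjusted p = 0.0195, or adjusted p = 0.671 with an estimated correlation), with 19 of 21 members higher and a median of 0.13. Its pair medians were 0.255 and 0.228 in KO1 and −0.0302 in KO2. The endoplasmic reticulum chaperone HSPA5 averaged 215 ± 74.3 against 174 ± 60.6 CPM, and CANX 1217 ± 44.4 against 1208 ± 89.1. The call of this list ended without parental 1 (adjusted p = 0.366), without parental 2 (0.0728), without KO1-2 (0.211), without KO2-1 (0.109) and under TMM or RLE scaling (0.0539 and 0.0532).

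All 13 mitochondrially encoded mRNAs were lower, with a median of −0.17 (adjusted p = 0.0195, or adjusted p = 0.857 with an estimated correlation). MT-CO1 averaged 1825 ± 218 CPM in UBR7KO and 1954 ± 70.7 in parental cells. The direction turned without parental 2 (adjusted p = 0.920) and without KO1-1 (0.448), and the call ended without parental 3 (0.0725) and under TMM or RLE scaling (0.0539 and 0.0532). Of the fibroblast markers, 4 of 5 were lower (adjusted p = 0.0202, or adjusted p = 0.775 with an estimated correlation), with COL1A1 at 7.64 ± 1.82 against 11.5 ± 0.971 CPM. COL1A1 lies on chromosome 17 between 20 and 90 Mb, where genes were lower by a median of −0.33 in the KO2 pair. COL1A1, COL3A1 and LUM also belong to the extracellular matrix list. The fibroblast call ended with the block (adjusted p = 0.0567), and without parental 1 (0.0681), parental 2 (0.0582), parental 3 (0.151) or KO2-1 (0.440). None of these 4 lists had a member called over all genes or adjusted over the list alone, and fry called none of the 26 tested lists. In the dated pairs 3 p53 targets (EDA2R, DDB2 and AEN) fell over all genes and 5 adjusted over the list alone, 3 unfolded protein response genes rose and 5 adjusted over the list alone, and 2 mitochondrially encoded mRNAs fell and 3 adjusted over the list alone.

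With the date pair as a block, replacement histone variants (adjusted p = 0.0253) and mitosis genes (0.0459) were also called higher, each with an adjusted p = 0.813 with an estimated correlation. H3F3B, the most expressed replacement variant, averaged 310 ± 28.6 CPM in UBR7KO and 353 ± 23.5 in parental cells, against the direction of its list, and TOP2A, the most expressed mitosis gene, 628 ± 240 against 574 ± 104. Both lie on chromosome 17 between 20 and 90 Mb, where genes were lower by a median of −0.33 in the KO2 pair. Without parental 1 the direction of the mitosis list turned (adjusted p = 0.102). Extracellular matrix genes were called higher in the dated pairs (adjusted p = 8.58e-09, or adjusted p = 0.901 with an estimated correlation). Of 28 members, 14 rose and 2 fell over all genes, and 18 rose and 3 fell adjusted over the list alone, with COL4A2 higher by 0.79, NID1 by 0.62 and TIMP1 by 0.60 and SPARC lower by −1.02. The median of this list was 0.41 (0.414) and 0.42 in the KO1 pairs and −0.30 in the KO2 pair. HOX genes were called lower in the dated pairs (adjusted p = 5.37e-07, or adjusted p = 0.901 with an estimated correlation), with 4 members lower over all genes (HOXA10, HOXA5, HOXA6 and HOXC4) and 6 adjusted over the list alone. Their median was −0.36 and −0.19 in the KO1 pairs and 0.34 in the KO2 pair. In the dated pairs mitosis genes (adjusted p = 9.41e-05), hypoxia and glycolysis genes (0.00153), replacement histone variants (0.00762), cholesterol synthesis (1.05e-07) and the unfolded protein response (0.000625) were also called higher. The p53 targets (2.04e-07), mitochondrially encoded mRNAs (7.62e-05) and the ZNF family (0.00203) were called lower there. Each had an adjusted p = 0.901 with an estimated correlation, or adjusted p = 0.937 for hypoxia and glycolysis and for the ZNF family.

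**Figure D2:**
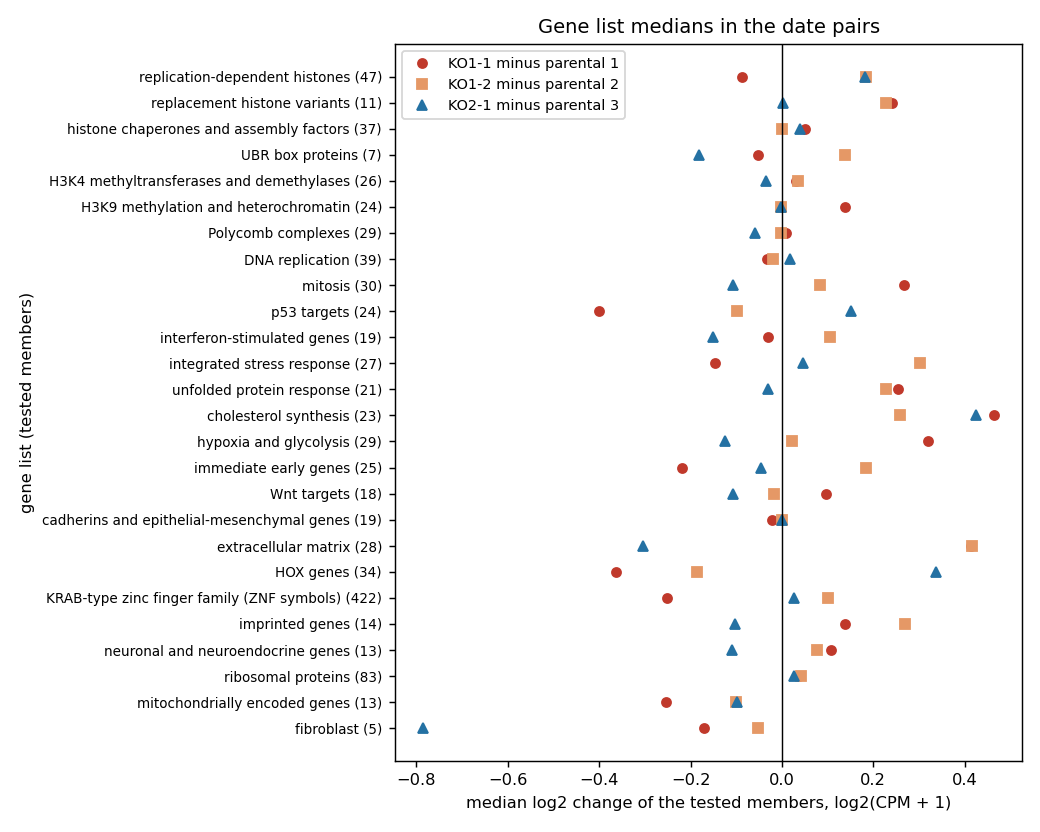
Median log2 change of the tested members of each gene list, 1 point per date pair, on the log2(CPM + 1) scale with the number of members in brackets. Cholesterol synthesis lies above 0 in all 3 pairs (0.464, 0.258 and 0.425), while extracellular matrix and HOX genes lie on opposite sides of 0 in the KO1 pairs and the KO2 pair.

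Genes that handle histones did not pass the test over all 6 libraries. NASP, an H3-H4 chaperone, averaged 281 ± 85.2 CPM in UBR7KO and 308 ± 107 in parental cells, ASF1A 28.7 ± 4.12 against 31.0 ± 7.52, and ASF1B 66.1 ± 6.79 against 56.6 ± 5.55. The CAF-1 subunit CHAF1A averaged 132 ± 21.5 against 130 (129.5) ± 20.1 CPM. HIRA, which deposits H3.3, averaged 18.1 ± 4.92 against 15.0 ± 1.10 CPM, with its highest level in KO2-1 at 23.8 CPM. The limma adjusted p was 1 for each, and CDH4 was not among the genes of the table. HIRA lies in a bin of chromosome 22 (10 to 20 Mb) whose genes were higher by a median of 0.271 in the KO2 pair. The camera adjusted p was 0.743 for histone chaperones and assembly factors, with NPM1 at a log2 change of −0.0151, and 0.369 for replication-dependent histones, with HIST1H1E at −0.0630. It was 0.549 for UBR box proteins, 0.796 for H3K4 methyltransferases and demethylases (PSIP1, 0.0114), 0.796 for H3K9 methylation and heterochromatin (SMARCA5, 0.11) and 0.566 for Polycomb complexes (BCOR, −0.0485).

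Among other lists, the camera adjusted p was 0.549 for DNA replication (MCM7, log2 change 0.0394), 0.0771 for mitosis, 0.524 for interferon-stimulated genes, 0.566 for the integrated stress response (XPOT, 0.0120) and 0.124 for hypoxia and glycolysis (GAPDH, 0.00836). It was 0.549 for immediate early genes (JUN, 0.0114), 0.124 for Wnt targets (LEF1, 0.0289), 0.0771 for cadherins and epithelial-mesenchymal genes (VIM, 0.21), 0.194 for extracellular matrix (LAMC1, 0.12) and 0.124 for HOX genes (HOXB9, −0.00474). It was 0.137 for the ZNF family (ZNF24, 0.00860), 0.369 for imprinted genes (GNAS, 0.37), 0.658 for neuronal and neuroendocrine genes (NEFM, −0.26), 0.823 for ribosomal proteins (RPS4X, 0.0161) and 0.124 for replacement histone variants. In the list of Wnt targets 1 member, SFRP1, fell adjusted over the list alone, and 0 members of any list passed over all genes. The median and the direction of the test differed in sign for Wnt targets (median 0.00548, mean −0.10), interferon-stimulated genes (0.0360, −0.0557), UBR box proteins (0.0155, −0.0877) and neuronal genes (−0.0250, 0.0467). Protocadherin clusters (2 tested members, PCDHGA11 at 0.0941), blood markers (2, CORO1A at −6.00e-04), cancer-testis antigens (1, SSX2IP at −0.0187) and keratinocyte markers (1) were too few to test, and no spike-in marker can be read from a human table.

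Several lists not called over all 6 libraries were called at the preset correlation once 1 library was left out. An estimated correlation was not run for these fits, and no list passed with it over all 6 libraries (replication-dependent histones, adjusted p = 0.874), with the block (0.813) or in the dated pairs (0.939). Replication-dependent histones were called higher without KO1-2 (limma camera adjusted p = 5.39e-09), parental 1 (0.000196) or parental 3 (0.0248), and lower without parental 2 (0.000515). Histone chaperones and assembly factors were called higher without KO1-1 (0.0162), and replacement histone variants without parental 3 (0.0414) or KO1-2 (0.0176). Ribosomal proteins were called higher without parental 1 (0.0151) or KO1-2 (0.000315) and lower without parental 2 (0.0329) or KO1-1 (0.00281). The integrated stress response was called higher without parental 1 (3.56e-05) or KO2-1 (0.00815) and lower without parental 3 (0.0394) or KO1-1 (0.0242), and the ZNF family higher without parental 1 (0.0429) and lower without parental 2 (0.00763) or 3 (0.00575). Mitosis genes were called higher without parental 2 (0.00361), parental 3 (0.000983) or KO1-1 (0.00281), and hypoxia and glycolysis genes without parental 2 (0.00311) or KO2-1 (0.0354). Wnt targets were called lower without parental 1 (0.00873), cadherins and epithelial-mesenchymal genes without parental 1 (0.00873) or KO1-2 (0.00358), and HOX genes without parental 3 (0.00777) or KO2-1 (0.00275). Extracellular matrix (3.41e-05) and imprinted genes (0.0409) were called higher without KO2-1, and neuronal and neuroendocrine genes without parental 2 (0.0428). Leaving out 1 library breaks a date pair, and 4 of these lists were called in opposite directions.

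ATAC-seq compared open chromatin between UBR7KO and parental cells. The UBR7KO ATAC libraries were inferred to come from line KO2, where UBR7 RNA stood at 1.08 of the parental mean, so a loss of UBR7 in these cells is not shown here. Of 13697 tested gene starts, 7243 were open in all 4 libraries, 106 in both UBR7KO libraries alone and 8 in both parental libraries alone. The 106 included the starts of EHMT2, which encodes an H3K9 methyltransferase, CDK4, TP73, BMP7, CXCL12 and MARVELD2. EHMT2 lies on chromosome 6, as do TEAD3, TRAF3IP2, MDGA1, CDKAL1, PPP1R18 and HCP5 of the 106. That chromosome holds a stretch higher in the KO2 pair in RNA and ATAC, given under other observations. Most of the 106 lie on other chromosomes. The 8 were SRCIN1, SYTL4, FRMD4B, RPL23, PI4K2A, PKIG, ZNF830 and LINC00632, of which SRCIN1, RPL23 and ZNF830 lie on chromosome 17. By replicate number, 1098 starts were open in both replicate 2 libraries alone and 2 in both replicate 1 libraries alone. The named starts were chosen after the lists were seen.

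The parental libraries held 10507 and 38529 ATAC peaks and the UBR7KO libraries 15310 and 45920 for replicates 1 and 2. They covered 4806133, 15667630, 8091402 and 17379744 bp, with median widths of 393, 307, 462 and 266 bp. UBR7KO libraries held 1.46 and 1.19 times as many peaks as the parental library of the same replicate number, and covered 1.68 and 1.11 times the length. Replicate 2 held 3.67 times as many peaks as replicate 1 in parental cells and 3.00 times as many in UBR7KO, so the replicate numbers differed more than the groups. With 2 libraries a group no permutation test can pass 0.05, and the read depth is unknown.

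Of the 59263 regions in the union of the 4 lists, 8794 were in every library, 588 in both UBR7KO libraries alone, 97 in both parental libraries alone and 10964 in both replicate 2 libraries alone. Within 1 kb of a gene start lay 71.6% of the regions in every library and 17.5% of those in both UBR7KO libraries alone. Of the shorter list, 94.0% overlapped within parental cells and 93.3% within UBR7KO, and between groups 83.6% and 67.1% for replicates 1 and 2, 94.7% for parental 1 with UBR7KO 2 and 90.3% for parental 2 with UBR7KO 1. Pairs of a replicate 1 and a replicate 2 library thus overlapped about as much between groups as within them. Circular shifts gave means of 0.541% to 1.44% for the 5 pairs in which the shorter list was shifted, and parental 2 with UBR7KO 1 has no such value. The authors' replicate-intersected sets held 9933 parental regions, 87.6% of them overlapping the UBR7KO set, and 14517 UBR7KO regions, 60.0% overlapping the parental set. Of the 5811 UBR7KO regions outside the parental set, 750 had no peak in either parental library, and of the 1231 parental regions outside the UBR7KO set 122 had none in either UBR7KO library. In the authors' cluster 1 of gene starts (2581 starts), 23.8% were open in parental replicate 1, 97.3% in parental replicate 2 and 100% in both UBR7KO libraries. In clusters 2, 3 and 4, 80.7%, 79.6% and 90.5% were open in parental replicate 1 and 98.8%, 98.5% and 95.8% in parental replicate 2. In both UBR7KO libraries 100% of clusters 2 and 3 were open as well, and 88.1% and 96.4% of cluster 4. Cluster 1 thus stood apart by its share in parental replicate 1, the library with the fewest peaks.

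RNA was compared at the starts that gained or lost an ATAC peak. The 106 genes open in both UBR7KO libraries alone had a median log2 RNA change of 0.09, against 0.01 (0.0145) for all tested genes, and the 8 genes open in both parental libraries alone a median of −0.15. In the undated pair 72 of the 106 (67.9%) and 1 of the 8 were higher in KO2-1, against 47.2% of all tested genes. In the KO1 pairs the medians of the 106 were 0.0223 and 0.0275, against −0.00282 and 0.0672 for all tested genes. Camera gave p = 0.0127 for the 106 (adjusted p = 0.101, or 0.923 with an estimated correlation) and p = 0.103 for the 8 (adjusted p = 0.292, or 0.923 with an estimated correlation). The 4 deposited clusters had adjusted p = 0.825 each, and the starts open in both replicate 2 libraries alone 0.825. The direction for the 106 turned without parental 3 (limma camera adjusted p = 0.818) and in the 2 dated pairs (adjusted p = 0.983), and their adjusted p was 0.00266 without parental 1 and 0.0455 without KO1-2. For the 8 the limma camera adjusted p was 0.0482 without KO1-2, and the direction turned without KO2-1 (adjusted p = 0.888). Across 13697 genes the change in open starts and the RNA change had a Spearman correlation of 0.046, and −0.000772 in the dated pairs, where genes are not independent replicates.

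ChIP-seq of GFP asked where UBR7 sits on chromatin. The peak with the highest score (1227) lay on chromosome 21 at 9825442 to 9827641 over MIR3648 and MIR3687, and was open in all 4 ATAC libraries. The next lay on chromosome 11 at 11268032 to 11268580 (1102), 23843 bp from GALNT18, and on chromosome 7 at 157253896 to 157254276 (957), 43763 bp from DNAJB6, and neither was open in any ATAC library. A peak on chromosome 20 at 1447334 to 1447842 (660.3) lay in NSFL1C and was open in all 4, and a peak on chromosome 22 at 38851401 to 38852385 (647) lay 196 bp from KCNJ4 and was open in parental replicate 2 alone. No peak lay in UBR7. The list held 5895 peaks with a median width of 203 bp, and 59.5% of them (Wilson 95% interval 58.2 to 60.7) lay within 1 kb of a gene start, against a mean of 1.203% and a highest value of 2.07% in circular shifts. Peaks in either parental ATAC library overlapped 70.4% of them (69.2 to 71.5), and peaks in either UBR7KO library 75.5% (74.4 to 76.6), against 0.953% and 1.07% in shifts. By library the shares were 37.6% and 68.9% for parental replicates 1 and 2 and 55.4% and 72.7% for UBR7KO replicates 1 and 2, in the order of their peak numbers. There was 1 GFP library and no replicate check. The series holds no GFP IP of cells without the tag. Circular shifts compare the peaks with random positions. They thus cannot part UBR7 binding from background signal at open chromatin and gene starts.

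**Figure D3:**
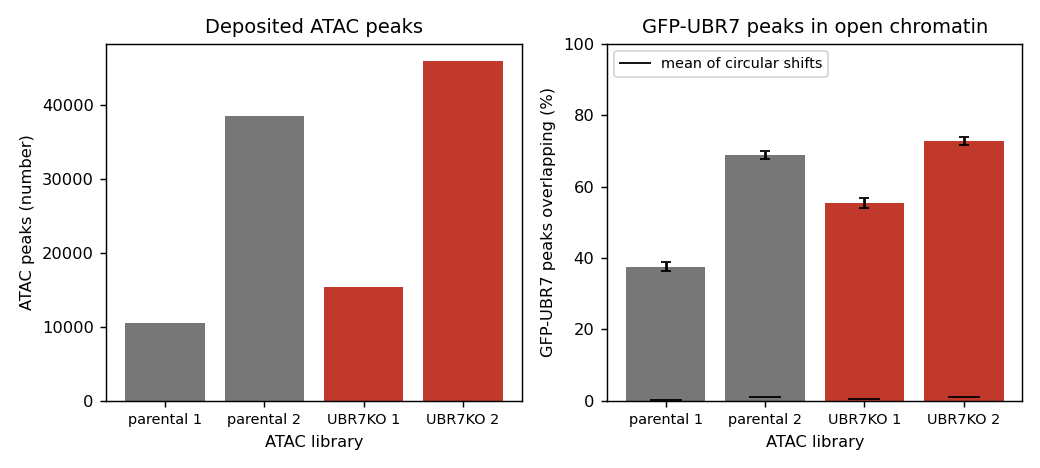
Left, number of deposited ATAC peaks in each of the 4 libraries; right, percent of the 5895 GFP-UBR7 peaks that overlap a peak of each library, with Wilson 95% intervals and the mean of circular shifts as black lines. The shares were 37.6% and 68.9% for parental replicates 1 and 2 and 55.4% and 72.7% for UBR7KO replicates 1 and 2, in the order of the peak numbers.

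Genes for H3K4 methyltransferases and demethylases carried a GFP-UBR7 peak at the start in 15 of 26 cases (57.7%), against 24.8% of other tested genes. This share passed Fisher's exact test over the 26 lists (adjusted p = 0.00946) and not the comparison with random lists of like expression (adjusted p = 0.0728). Among members with such a peak, PSIP1 encodes a reader of H3K36 methylation. Replication-dependent histones had a peak in 5 of 47 cases (adjusted p = 0.183 by Fisher's exact test and 0.0728 by matched lists), and imprinted genes in 0 of 14 (0.183 and 0.233). For the other lists the adjusted p ran from 0.183 to 1 by Fisher's exact test and from 0.151 to 1 by matched lists. The genes with a peak at the start had a median level of 30.8 CPM, and those without 20.4 CPM.

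RNA of the genes with a GFP-UBR7 peak was then compared between UBR7KO and parental cells. The 4312 genes with a peak at the start or in the gene had a median log2 change of 0.03, and all tested genes 0.01 (0.0145). Camera gave p = 0.109 (adjusted p = 0.292, or 0.923 with an estimated correlation). Of the 4312 genes 0 were called by limma over all 6 libraries, and 11 had an unadjusted p under 0.05, against 20.0 in random lists of like expression (95% of lists from 13 to 27). With the block 242 did, against 244 (219 to 269). In the dated pairs 145 were called, against 160.6 (141 to 180). Of all 13697 tested genes, 3408 carried a peak at the start. Of the 20 genes with the largest changes in the dated pairs, APC2 and CPPED1 carried one. So did CHAF1A, ASF1A, ASF1B, LAMC1 and PSIP1, while NASP, HIRA, UBR7, SFRP1, BMP2, SNX19, BEX1 and ZNF462 did not. Histone chaperones and assembly factors carried a peak at the start in 8 of 37 cases (21.6%), against 24.9% of other tested genes.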

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

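The tests of the difference between lines, of mislabelled and of exchanged libraries were chosen after the results they address were seen. The change in UBR7KO differed between the KO1 pairs (2 libraries) and the KO2 pair (1 library) for 30 named genes, tested with the date pair as a block (limma, 1 residual degree of freedom, with the spread taken from the 2 KO1 pairs alone). It differed for 6 gene lists at the preset correlation and for none with an estimated correlation (adjusted p = 0.843 for each). Values are KO2 minus KO1 differences of the log2 change. KO2 exists only in the undated pair, so line and preparation cannot be parted, and a difference here is one between pairs. Of the named genes, those with the largest changes in the dated KO1 pairs were picked by those changes, so a difference from KO2 was partly built into the choice. No biological difference between the lines is named in the design, and none was tested.

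UBR7 itself differed by 1.16 (1.155). Genes with a higher change in KO2 were MARVELD2 (4.46), ESRP2 (3.24), CTSZ (3.20), PTPRM (3.16), RP11-453F18__B.1 (1.98), CPPED1 (1.84), ACSS3 (1.59), MGST1 (1.38), STMN3 (1.28), FADS2 (1.16) and COL2A1 (1.14). Genes with a lower change in KO2 were DDR2 (−5.84), SYTL5 (−4.29), MXRA8 (−3.94), MID1 (−3.27), ZNF462 (−2.51), MLLT11 (−2.43), APC2 (−2.41), COL6A3 (−1.94), DAB2 (−1.90), BEX1 (−1.62), NES (−1.51), TPM2 (−1.47), NEFM (−1.26), LAMC1 (−1.17), RAP1GAP2 (−1.04), VIM (−1.04), TMCO3 (−1.01) and TOP2A (−0.83). BEX1, ZNF462, TPM2, DAB2 and RAP1GAP2 stood below the parental partner in every pair, and COL2A1, STMN3 and FADS2 above it, each with its largest change in the KO2 pair. ACSS3, MGST1, CPPED1 and RP11-453F18__B.1 also stood below it in every pair, and APC2 and TMCO3 above it, each with its smallest change in the KO2 pair. TOP2A lies in the chromosome 17 stretch lower in the KO2 pair, and LAMC1 in the chromosome 1 stretch higher in KO1, both given under other observations. NES, MLLT11 and DDR2 also lie on chromosome 1, TPM2 on chromosome 9 and RAP1GAP2 on chromosome 17. Each of these chromosomes holds bins shifted in the KO1 pairs. The other named genes are not set against the stretches here. For TPM2 and BEX1 the larger change in the KO2 pair came from parental 3, at 42.2 and 26.5 CPM against 10.52 to 10.98 and 6.82 to 6.89 in the other parental libraries, and not from a lower level in KO2-1 (6.54 and 1.98 CPM) than in KO1.

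By list, the median difference was −0.784 for extracellular matrix (camera adjusted p = 2.65e-14), 0.636 for HOX genes (5.62e-09), 0.425 for p53 targets (1.18e-05), −0.376 for mitosis (0.000775), 0.0758 for the ZNF family (0.00258) and −0.296 for hypoxia and glycolysis (0.00722).

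UBR7 RNA of the library labelled KO2 lay at the parental level, and changes across genes in the KO2 pair ran apart from those in KO1. A library of parental cells under the KO2 label would not share the lower RNA level of 16 chromosome bins with the ATAC libraries of UBR7KO cells, and these bins had a median log2 ATAC ratio of −0.50 in the replicate nearest 0 (−0.5015), which argues against that cause. Labels exchanged within the undated pair would turn the ratio positive, and in replicate 2 it was −0.79 (−0.7889). Both readings rest on correct labels of the ATAC libraries and on the inferred use of line KO2 for them. Chromosome stretches that shifted in 1 line would hide a shared change, and the correlation between lines stayed at −0.127 after bin medians were taken out, which argues against them as the cause. A frameshift that leaves the RNA in place and a difference of line or preparation that arose apart from UBR7 may account for the pattern and remain open, since KO2 has 1 library.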

How the results depend on the processing

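Alternatives on recovered reads other than DESeq2, the exact test, RLE and voom, on TMM-scaled values, on the dated pairs for lists and peaks, and for single pairs were chosen after the data were seen. For the 22 genes chosen for all 6 libraries, not all of them given above, 528 alternatives gave the same direction, 87 of them now past the threshold. The groups of these genes did not overlap, which was a rule of choice for those taken with the block. Their direction could thus hardly turn, so this count is no sign of stability. For 17 genes named for the dated pairs quasi-likelihood kept 16 past the threshold and left 1 short of it. Where no cause is given, the cause was not tested.

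Counts of called genes were 0 higher and 0 lower with each library left out in turn, with 49 to 257 genes at an unadjusted p under 0.05, the most without KO2-1. They were 1 and 6 with DESeq2, 0 and 6 with the exact and the likelihood ratio test, 305 and 186 in the 2 dated pairs and 238 and 244 there by quasi-likelihood. With the replicate block they were 19 and 40 by likelihood ratio, 12 and 26 by DESeq2 and 1 and 3 by limma on TMM-scaled values. UBR7 passed the threshold in the dated pairs alone, at −1.10, and −1.17 by quasi-likelihood, where the KO2 pair is left out.

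Camera called 2 lists higher and 3 lower. Higher and lower lists numbered 4 and 2 with the block, 6 and 4 in the dated pairs, 1 and 2 with RLE and with TMM scaling, and 4 to 5 and 3 to 4 with each library left out. With an estimated correlation or fry they were 0 higher and 0 lower, with the block and without it, and 0 and 0 in the dated pairs with an estimated correlation. The adjusted p with an estimated correlation was 0.0849 for cholesterol synthesis, 0.671 for the unfolded protein response, 0.775 for fibroblast markers and 0.857 for p53 targets and mitochondrially encoded mRNAs, and 0.813 for each with the block. In the dated pairs it was 0.901, and 0.937 for fibroblast markers, which had 0.837 there with the preset correlation and 0.0567 with the block. By fry it was 0.721 for cholesterol synthesis and 0.932 for the other 4, and with the block 0.210 for cholesterol synthesis, 0.533 for mitochondrially encoded mRNAs, 0.851 for the unfolded protein response, 0.876 for fibroblast markers and 0.889 for p53 targets. With RLE and TMM scaling the unfolded protein response and the mitochondrially encoded list had 0.0532 and 0.0539. With each library left out the p53 list ran from 1.68e-05 without parental 3 to 0.627 without parental 1, the unfolded protein response from 0.00281 without KO1-1 to 0.366 without parental 1, and fibroblast markers from 0.0108 without KO1-1 to 0.440 without KO2-1. The mitochondrially encoded list ran from an adjusted p of 1.76e-07 without KO1-2 to 0.920 without parental 2, and its direction turned there and without KO1-1 (0.448).

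The UBR7KO to parental ratio of mean peak numbers, 1.25, ran from 1.19 without replicate 1 to 1.46 without replicate 2, and that of covered length, 1.24, from 1.11 to 1.68. Overlap of the shorter list within groups, 93.7%, was 22.6% for equal numbers of top-scored peaks, 22.3% with a stricter q and 91.3% with 50% of the shorter peak covered. Between groups the mean of the 4 pairs, 83.9%, was 30.3% for top-scored peaks and 19.2% with a stricter q. With a replicate number left out only 1 such pair is left, at 67.1% or 83.6%. The −log10 q ranked shared peaks poorly, with Spearman correlations of 0.0389 to 0.0689 between libraries against 0.464 to 0.700 for width, so the q alternatives choose peaks nearly at random. The correlation of open starts with RNA, 0.046, was 0.0143 in the KO1-1 pair, −0.013 in the KO1-2 pair, 0.0722 in the KO2 pair and −0.000772 in the dated pairs, and ran from 0.00823 without KO2-1 to 0.0714 without KO1-2. The camera p of starts open in UBR7KO alone ran from 0.000333 without parental 1 to 0.716 without parental 3, where the direction turned, as in the dated pairs (0.657).

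The share of GFP-UBR7 peaks in open chromatin was 79.3% (parental) and 84.4% (UBR7KO) for the upper 50% of peaks by score, and 61.1% and 67.6% with 50% of the peak covered. The share near a gene start was 68.4% with a 5 kb window and 65.5% for the upper 50% of peaks. Not run were the ATAC value per gene region with its 3 alternatives and the twentieth in place of the tenth of regions, since the file holds no value, and the correlation in called genes, since 0 were called. Depth did not limit the named genes except SFRP1, and the ATAC and GFP depths are unknown.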

Other observations

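Runs of chromosome bins, the copy number test and both parts of the test of parental 3 split by direction were chosen after the data were seen. In the library labelled KO2, RNA from chromosome 2 between 0 and 90 Mb lay below parental 3 by a median of −0.37 over 370 genes, 87.0% of them in that direction. RNA from chromosome 17 between 20 and 90 Mb lay lower by a median of −0.33 over 621 genes, and RNA from chromosome 6 between 40 and 100 Mb higher by 0.25 over 174 genes. In KO1, RNA from chromosome 1 between 150 and 220 Mb lay higher by a median of 0.26 over 378 genes. These stretches are the longer runs of shifted bins, so shorter ones are left out. In the KO1 pairs chromosome 9 between 30 and 40 Mb lay at −0.485 and −0.563. The bins of chromosome 17 between 0 and 20 Mb ran from −0.323 to −0.220, and every bin of chromosome 10 lay above 0. Copy number was not tested for the KO1 shifts, since no ATAC library was inferred to come from KO1. Of 252 bins, 28 shifted by at least 0.2 in the KO2 pair, against at most 2 in 1000 random placements of the genes, and 16 and 15 did so in the KO1 pairs, against at most 5 and 2. ATAC peaks far from gene starts had log2 ratios of UBR7KO to parental of −0.63 and −0.85 in the chromosome 2 stretch, −0.26 and −0.78 in the chromosome 17 stretch and 0.99 and 0.56 in the chromosome 6 stretch for replicates 1 and 2.

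A candidate explanation of the KO2 stretches is a DNA copy number that differs between this line and parental cells. In the bins shifted in the KO2 pair, ATAC ratios had the direction of RNA. Their median log2 ATAC ratio was −0.50 and −0.79 in the 16 lower bins and 0.55 and 0.40 in the 12 higher bins (replicates 1 and 2). Over all 252 bins RNA and ATAC correlated at 0.270 and 0.287, above every rotation (highest 0.250 and 0.269). Both values lay under the bound of 0.3, set after the data were seen, so by that bound the copy number explanation stays open. Gene length and expression level as the whole cause are argued against, since 99.4% of the SD of bin medians was left after both were fitted. Bin medians of parental 3 minus the mean of parental 1 and 2 had an SD of 0.159, and those of KO2-1 minus parental 3 an SD of 0.135. The former compares libraries of different date pairs and the latter those of 1 pair. A deviation of parental 3 was undecided over all shifted bins (49.1% of the shift), argued against for the 16 lower bins (12.04%) and met for the 12 higher bins (112%). The higher RNA of chromosome 6 in KO2 may thus rest on its parental partner, although ATAC ratios there were positive.

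Other splits of the samples were tested as planned, and 10 splits cannot give a share under 0.05. The real split called 0 genes and the highest of the others 0, so 10 of 10 splits gave as many. The 6 splits that keep 2 date pairs whole gave 1130 to 2928 genes at an unadjusted p under 0.05, against 70, a structure of the samples. The highest set parental 1 and both KO1 libraries against the rest, while parental 1, parental 2 and KO1-1 against the rest kept the same pairs whole and gave 1389, so date pair and KO1 line were not told apart. Of the 4 splits that part every pair, 2 gave as many genes at an unadjusted p under 0.05 with the block (755 in the real one, 1606 with the KO2 pair turned). For called lists 9 of 10 splits gave as many (5 in the real one, 14 at most in the others). For genes with a GFP-UBR7 peak 1 of 10 splits gave a −log10 camera p as high (0.961 in the real one, 0.932 at most in the others).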
